A study of Mus musculus with 20 samples.

How the data were processed

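Whole ileum from male Ldlr-/- mice was profiled with Lexogen QuantSeq, a library type that reads the 3' end of polyadenylated transcripts, from 1 µg of total RNA per library, per the labels' protocols. The mice had been on the atherogenic diet for 1 week before exposure began. The deposited table holds raw counts, as whole numbers per gene and library, that the authors made with STAR (aligner) and HTSeq (read counting) on the mouse build mm10, per the submitters' processing notes. The same table carries the authors' edgeR result for each gene, with a log2 fold change and mean log2 CPM, a likelihood ratio score, a p-value and an adjusted p-value (FDR), per the file headers. Versions, aligner settings, gene annotation and the strand setting of the counting are not given in the sources used here. QuantSeq counts come from transcript ends, so they do not grow with transcript length, but reads of near-identical paralogs and of overlapping genes can be assigned to either gene or dropped. Use of molecular identifiers or removal of PCR duplicates is not given in the sources used here.

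Each column of counts matched 1 sample by its description in the labels, and 0 columns were left without a sample. Samples were grouped as control or PFAS from the labels, which number them 1 to 10 in each group. The names of the count columns number all control samples before all PFAS samples, in the same order. Sample order and group therefore cannot be told apart. Whether this numbering follows handling or sequencing is not given in the sources used here. The labels number the samples separately but do not name an animal for each, so the p-values measure the spread between these samples, which may be partly technical. No pair of libraries within a group was 1 library sequenced again, since the chi-square statistic per degree of freedom over genes lay between 4.28 and 20.9 for all 90 pairs. This does not show that the libraries came from separate animals. All libraries had counts from Y-linked genes (Ddx3y at 71.9 to 104 CPM) and at most 2.32 CPM of Xist, which matches the label male.

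Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group as factor (a count minimum of 10 and a total of 15), which left 12813 genes that held all but 0.603% of the counts. Libraries were scaled with TMM factors, and the groups were compared with a robust quasi-likelihood fit and F test without covariates. Standard errors of log2 fold changes were taken as the size of the change divided by the square root of the F statistic. P-values were adjusted by the Benjamini-Hochberg method, and genes under 0.05 were called. CPM values use the TMM-scaled library size, and log2 CPM values use a prior count of 2. The common biological coefficient of variation was 0.209. Genes that did not pass the filter included 9 with 0 counts in all control libraries and at least 3 counts in at least 3 PFAS libraries, and 13 with the reverse.

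Before the data were examined, 44 gene lists were written from textbook knowledge of ileum, bile acid and lipid handling, receptors that respond to PFAS, stress, immunity and the cell types that a piece of ileum can hold. Lists with at least 5 tested members, 40 in all, were tested with camera from limma 3.58.1 at its preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation, camera on ranks and fry were alternatives. A list's score in a library is the mean over its members of log2 CPM minus the gene's mean over all libraries. Named genes were the 12 with the largest positive and the 12 with the largest negative log2 fold change among called genes with a mean of at least 2 CPM, a set of focus genes (Slc10a2, Fabp6, Slc51a, Slc51b, Fgf15, Nr0b2, Nr1h4, Npc1l1, Abcg5, Abcg8, Hmgcr, Cyp4a10, Cpt1a, Pdk4 and Ldlr), and up to 4 members with the lowest p in each list. Other genes are said to be named after their values were seen. Gene positions come from the RefSeq annotation of GRCm38, the assembly that mm10 denotes.

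Alternatives fixed at the same time were other scaling (size factors, upper quartile, library size only), other tests (edgeR's likelihood ratio test, DESeq2 1.42.0, limma-voom with and without sample weights), other filters, the replicate number as a block, each library left out in turn, 1 surrogate variable from sva 3.50.0, and the 20 most abundant genes left out. Alternatives chosen after seeing the data set aside PFAS libraries 7 to 10, or control libraries 1 and 2 with PFAS library 10, removed each library's trend on transcript length in a limma-trend fit, or took a signed score of clock genes or the score of proximal small intestine markers as covariate. Transcript lengths were those of the longest GENCODE transcript of a symbol and were found for 94.0% of tested genes.

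The gene test was checked on simulated counts for 12813 genes in 10 against 10 libraries, drawn from the real means and library sizes, with 200 genes changed. It called 20% of genes changed 1.25-fold, 68% of those changed 1.5-fold, 88% of those changed 2-fold and 86% of those changed 3-fold. Of its calls 5.76% were unchanged genes and 0 had the wrong sign, and with nothing changed it called 0 genes. A 1.25-fold difference in a single gene was therefore mostly missed at this depth and spread.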

Results

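RNA was measured in the ileum, the last segment of the small intestine, of male mice that lack the low-density lipoprotein receptor (Ldlr-/-), a strain used to study diet-induced atherosclerosis. The mice ate an atherogenic diet with 0.15% cholesterol. They drank either control water or water with 5 per- and polyfluoroalkyl substances (PFAS) for 7 weeks, with 2 mg/L of each. The mixture held GenX, PFHxS, PFNA, PFOS and PFOA. There were 10 control and 10 PFAS libraries. The libraries held 3387099 to 6012178 counts, with a mean of 4283593 ± 752706 (SD, n = 10) in control and 4417749 ± 865066 (SD, n = 10) in PFAS. Of the 35976 genes listed, 25523 had at least 1 count and 12813 were abundant enough to test. Ldlr itself was counted at 6.41 ± 3.26 CPM (counts scaled to library size; SD, n = 10) in control and 8.05 ± 3.60 CPM in PFAS (adjusted p = 0.569). Its 3' tags can lie outside the disrupted part of the gene, so this count checks nothing about the genotype.

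The comparison of PFAS with control water asks which ileal transcripts differ after exposure, with the bile acid transporter ASBT (Slc10a2) named in the series title. The clearest difference was a fall of genes for burning fatty acids and making ketone bodies. Hmgcs2, the rate-limiting enzyme of ketone body synthesis, fell from 313 CPM in control to 73.8 CPM in PFAS, a log2 fold change of -2.08 ± 0.16 (SE, n = 10 and 10; adjusted p = 4.27e-08). The acyl-CoA thioesterases Acot1 (-1.88 ± 0.18) and Acot2 (-1.31 ± 0.15) fell too. Each of these 3 genes was lower in 10 of 10 PFAS libraries than in any control library. In the other direction, the antimicrobial lectins Reg3g (1.39 ± 0.25) and Reg3b (1.22 ± 0.21) rose 2.62-fold and 2.33-fold, and the bile acid exporter genes Slc51a and Slc51b and the bile acid receptor gene Nr1h4 (FXR) rose by 0.38, 0.55 and 0.56 on the log2 scale.

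Targets of the fatty acid receptor PPARα and enzymes of fatty acid oxidation formed the list with the lowest camera p and the most called members. Of its 48 tested members, 27 fell, 0 rose and 21 were not called, with a median log2 fold change of -0.41. Adjusted over the list alone, 34 were lower and 1 was higher. Hadha, the alpha subunit of the mitochondrial trifunctional protein, fell from 491 to 288 CPM (log2 fold change -0.77 ± 0.07, SE, n = 10 each, adjusted p = 6.47e-09). Abcd3, a peroxisomal transporter of fatty acids, fell by 0.68 on the log2 scale (adjusted p = 8.13e-07), and Cpt1a, which commits fatty acids to mitochondrial oxidation, fell by 0.57 (adjusted p = 2.64e-04). Retsat, retinol saturase, fell by 1.15. Ppara, the gene of the receptor itself, named after its values were seen, fell by 0.48 (adjusted p = 0.0151). Pdk4, which restrains glucose oxidation, had a log2 fold change of -1.14 ± 0.46 at 4.20 CPM in control and was not called (adjusted p = 0.148). It was called lower under 2 of 16 alternatives other than leaving out 1 library, and in 0 of the 20 fits without 1 library. Cyp4a10, a fatty acid hydroxylase, did not pass the count filter used here. It had 214 counts over the 10 control libraries (1 to 47 each) and 31 over the 10 PFAS libraries (0 to 11 each). The authors' deposited likelihood ratio test gives it a log2 fold change of -2.76 with an adjusted p of 0.00634. Camera called the list lower (adjusted p = 1.56e-41), and the call held at adjusted p = 5.14e-05 with an estimated correlation between genes. In the same libraries the absorptive enterocyte markers had a median log2 fold change of 0.18. Acot1 and Acot2 are close paralogs on chromosome 12 (positions 84009502 to 84017670 and 83987861 to 83993877 of mm10), and reads shared between them are uncertain.

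**Figure D1:**
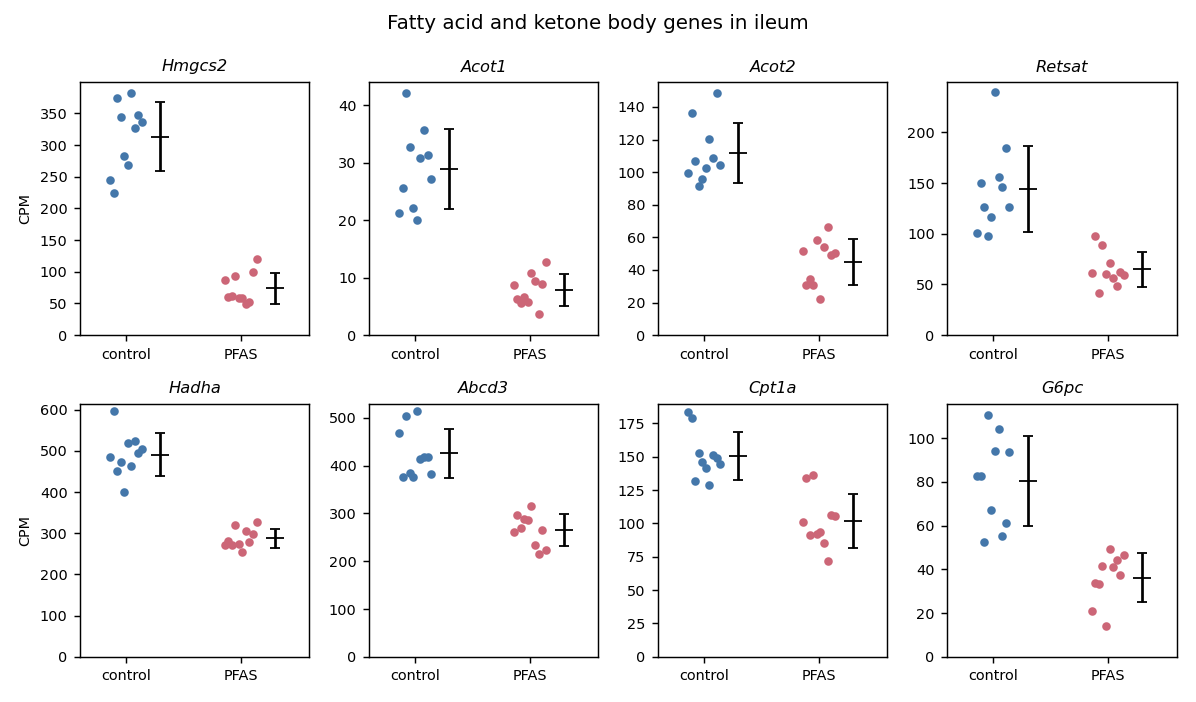
CPM (counts scaled to library size, linear axis from 0) of 8 genes in each of the 10 control and 10 PFAS libraries; points are libraries, and the horizontal mark and bars give the mean and SD. PFAS libraries lie below the control libraries without overlap for Hmgcs2, Acot1, Acot2, Retsat, Hadha, Abcd3 and G6pc. The groups overlap for Cpt1a, and Retsat and G6pc separate by a narrow gap. Hmgcs2 goes from a mean of 313 to 73.8 CPM.

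The list of ileal bile acid transport and FXR pathway genes had 3 members that rose, 0 that fell and 15 that were not called, out of 18. Slc51a (chromosome 16, 32475578 to 32487879), 1 subunit of the basolateral bile acid exporter, rose from 1205 ± 74.3 CPM to 1566 ± 175 CPM (SD, n = 10 each; adjusted p = 9.87e-04), and all 10 PFAS libraries exceeded every control library. Slc51b (chromosome 9, 65412753 to 65422773), its partner subunit, rose 1.46-fold (adjusted p = 0.00195), and Nr1h4 (chromosome 10, 89454234 to 89533645) rose 1.47-fold (adjusted p = 5.74e-04). Slc10a2 (chromosome 8, 5083219 to 5105287), which carries bile acids from the lumen into the enterocyte, was 408 ± 91.1 CPM in control and 630 ± 220 CPM in PFAS, a log2 fold change of 0.63 ± 0.19. It lay above the control median in 9 of 10 PFAS libraries and did not pass the quasi-likelihood test (adjusted p = 0.0610). The authors' deposited table gives Slc10a2 a log2 fold change of 0.63 with an adjusted p of 0.0138. An edgeR likelihood ratio test (adjusted p = 0.0216) and DESeq2 (adjusted p = 0.0213) also called it, as did the quasi-likelihood fit without PFAS library 9 (adjusted p = 0.0245). The same fit called it without PFAS libraries 7 to 10 (0.0171), with the proximal score as covariate (0.0170) and with the replicate number as block (0.0162). Over the alternatives, fits without 1 library included, its adjusted p ran from 0.0162 to 0.114, except with a score of clock genes as covariate. There it was 0.998 with a log2 fold change of -0.01. The grouping accounted for 0.844 of the variance of that score and the fit called 0 genes, so the loss is not particular to Slc10a2. Fabp6, the ileal bile acid binding protein, was abundant at 6953 ± 2188 CPM in control and 7110 ± 1196 CPM in PFAS (log2 fold change 0.03, adjusted p = 0.946). Fgf15, the hormone that ileal FXR induces, had a log2 fold change of -0.46 ± 0.34 (adjusted p = 0.497). Nr0b2 (SHP), an FXR target, had 28 counts in control and 15 in PFAS and was not tested. Adjusted over the list alone, 4 members were higher. Camera called the list higher (adjusted p = 0.0172), with adjusted p = 0.331 with an estimated correlation. Its median log2 fold change was 0.05, or -0.03 with library size as the only scaling. It was 0.12 without PFAS libraries 7 to 10, 0.17 without control 1, control 2 and PFAS 10, and 0.14 with the proximal score as covariate.

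**Figure D2:**
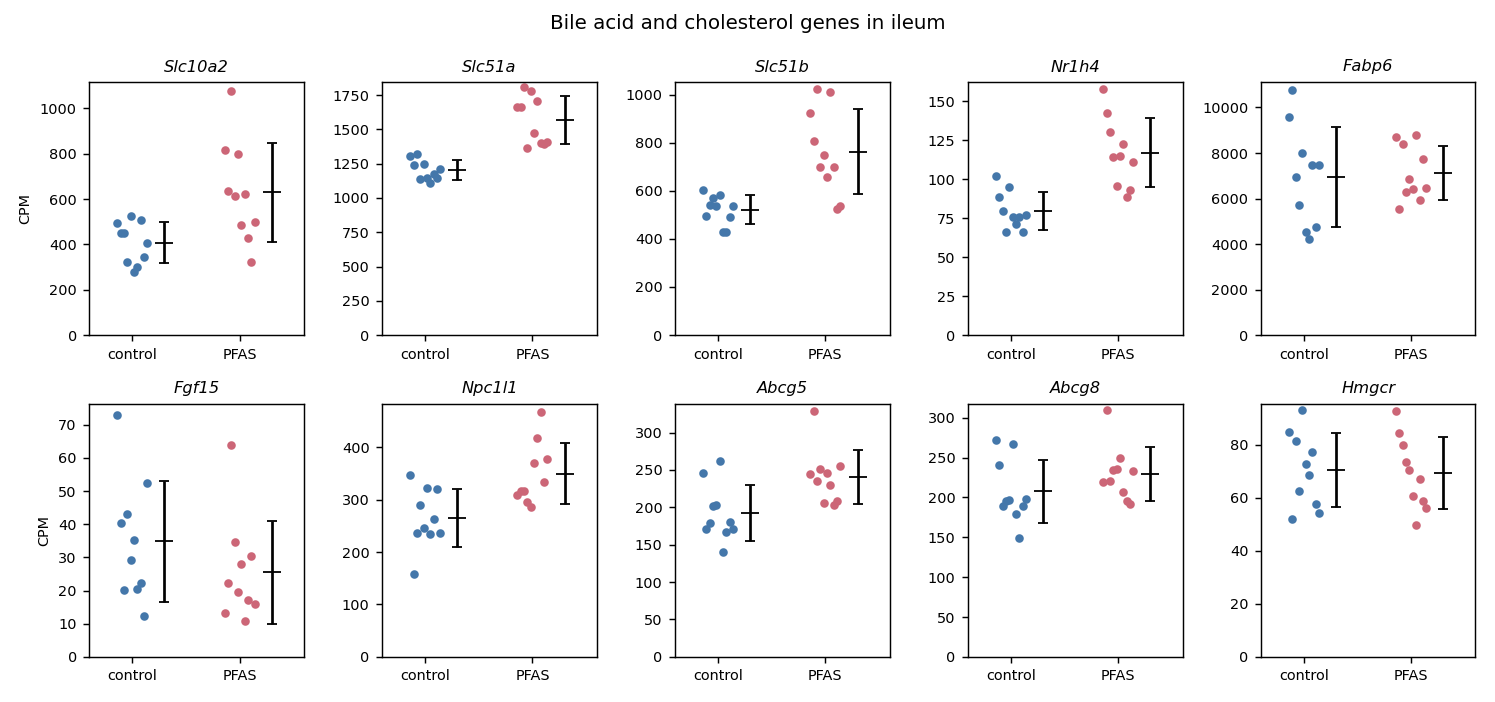
CPM (counts scaled to library size, linear axis from 0) of 10 bile acid and cholesterol genes in each of the 10 control and 10 PFAS libraries; points are libraries, and the horizontal mark and bars give the mean and SD. Slc51a separates the groups, Slc10a2 spreads more widely in PFAS (SD 220 CPM) than in control (SD 91.1 CPM), and Fabp6 and Hmgcr overlap.

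Among 18 genes of cholesterol absorption and efflux, 2 rose and 16 were not called, the same counts as adjusted over the list alone. Npc1l1, the cholesterol importer of the brush border, rose from 266 ± 55.7 CPM to 349 ± 58.4 CPM (SD, n = 10 each; log2 fold change 0.40 ± 0.11, adjusted p = 0.0332). Abcg5, a subunit of the sterol exporter of the same membrane, rose by 0.32 ± 0.10 (adjusted p = 0.0418), while its partner Abcg8 had 0.14 ± 0.09 (adjusted p = 0.430). With single libraries left out, the adjusted p of Npc1l1 reached 0.0664 and that of Abcg5 0.0956. This list was not called (camera adjusted p = 0.244). None of the 23 tested genes of cholesterol biosynthesis was called, 3 were higher adjusted over the list alone, and Hmgcr, the rate-limiting enzyme, had a log2 fold change of -0.02 ± 0.11 (adjusted p = 0.952). The biosynthesis list was called higher as a set (camera adjusted p = 0.0324, median 0.14), with adjusted p = 0.686 with an estimated correlation. This call was lost in 8 of the 20 fits without 1 library, with adjusted p up to 0.107.

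Of 18 tested genes of the circadian clock 7 rose, 1 fell and 10 were not called, and adjusted over the list alone 9 were higher and 3 lower. Usp2 rose from 120 ± 14.4 CPM to 204 ± 44.6 CPM (SD, n = 10 each; adjusted p = 1.20e-05), with every PFAS library above every control library. Nr1d2 (REV-ERBβ, a repressor of the clock) rose by 0.71 ± 0.10, Tef by 0.79 ± 0.13 and Per3 by 0.82 ± 0.16 on the log2 scale. Nfil3, a repressor that acts opposite to Tef and was named after its values were seen, fell by 0.85 (adjusted p = 0.0281). Camera called the clock list higher (adjusted p = 5.98e-06, median 0.44), with adjusted p = 0.0970 with an estimated correlation. The labels used here do not give the hour of tissue collection. A signed clock score (output and repressor genes minus activator genes and Nfil3), made after the data were seen, separated the groups completely. The score of the clock list fixed beforehand overlapped, at 0.095 in control library 5 against -0.129 in PFAS library 9. With the signed score as covariate edgeR called 0 genes, 1101 had an unadjusted p under 0.05 and camera called 8 lists. Of these, 4 were among the 15 called without it, the PPARα list included (adjusted p = 2.01e-13).

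Of 16 tested epithelial antimicrobial genes 4 rose and 12 were not called, and adjusted over the list alone 6 were higher and 1 lower. Reg3b rose from 9118 ± 2804 CPM to 21237 ± 6662 CPM and Reg3g from 3689 ± 1056 CPM to 9684 ± 3966 CPM (SD, n = 10 each; adjusted p = 0.00195 and 0.00348). Duox2, an oxidase of the gut surface, rose 2.08-fold (adjusted p = 0.0483), and Lypd8, which keeps bacteria off the epithelium, rose 1.28-fold (adjusted p = 0.0123). The call of Duox2 was lost in 15 of the 20 fits that left out 1 library, with adjusted p up to 0.0922. Camera called the antimicrobial list higher (adjusted p = 0.00175, median 0.31), with adjusted p = 0.331 with an estimated correlation. PFAS libraries 7, 8 and 9 had the highest scores on it (0.57, 0.52 and 0.44), and without PFAS libraries 7 to 10 the list was not called (adjusted p = 0.147, median 0.16), while Reg3b (1.04) and Reg3g (1.08) were still called higher and Itln1, named after its values were seen, was called lower (adjusted p = 0.0417, against 0.626 with all libraries). Reg3b and Reg3g are paralogs, and so are Saa1 and its neighbours, so their split of reads is uncertain.

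Inflammatory mediators had 3 of 13 tested members higher and 10 not called, the same counts as adjusted over the list alone. Saa1, an acute phase protein, rose 2.85-fold to 473 ± 288 CPM (SD, n = 10; adjusted p = 0.0358), Nfkbia, the inhibitor of NF-κB, rose by 0.39 ± 0.09 and Il18 by 0.59 ± 0.16 on the log2 scale. Saa1 lost its call in 7 of the 20 fits without 1 library (adjusted p up to 0.0711), and Il18 in 12 of them. Camera called this list higher (adjusted p = 0.0193, median 0.20), with adjusted p = 0.0970 with an estimated correlation. Without PFAS libraries 7 to 10 it was not called (adjusted p = 0.0746, median 0.07), and Nfkbia was the 1 member called. Of 35 interferon response genes 4 rose and 31 were not called (5 higher adjusted over the list alone). Ifit1 rose by 0.96 ± 0.21, Oasl2 by 0.68 ± 0.15, Ifit1bl1 by 0.84 ± 0.23 and Irf7 by 0.43 ± 0.11. The interferon list was called higher (camera adjusted p = 9.80e-04, median 0.15), with adjusted p = 0.350 with an estimated correlation. Socs3, which dampens cytokine signalling, rose 2.21-fold (adjusted p = 0.0143), and Nfkbie rose by 1.22 ± 0.36 (adjusted p = 0.0438).

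Markers of the cell types in the ileal wall differed between the groups as well. Of 28 fibroblast and matrix genes 5 fell and 23 were not called (10 lower adjusted over the list alone). The collagens Col1a2 (-0.56 ± 0.09), Col1a1 (-0.45 ± 0.11), Col3a1 (-0.41 ± 0.09) and Col6a2 (-0.38) fell, as did Dpt (-0.42 ± 0.11), which binds collagen. Camera called that list lower (adjusted p = 5.98e-06, median -0.21), with adjusted p = 0.0970 with an estimated correlation. Among 21 smooth muscle markers Acta2 (-0.26 ± 0.07) and Myh11 (-0.24 ± 0.07), smooth muscle actin and myosin, fell and 19 were not called, with 8 lower adjusted over the list alone. The muscle list was called lower (camera adjusted p = 0.00253, median -0.13), with adjusted p = 0.361 with an estimated correlation. Of 33 proliferation genes 5 fell and 28 were not called (7 lower adjusted over the list alone), namely Mki67 (-0.40 ± 0.10), Top2a (-0.43 ± 0.10), Mcm7 (-0.47 ± 0.10), Kif11 (-0.74 ± 0.19) and Nusap1 (-0.40). The proliferation list was called lower (camera adjusted p = 5.76e-05, median -0.20), with adjusted p = 0.332 with an estimated correlation. Crypt base stem cell markers had 0 of 16 members called (camera adjusted p = 0.497). Col6a2 and Nusap1 were named after their values were seen.

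Absorptive enterocyte markers went the other way, with 7 of 24 higher and 17 not called (8 higher and 1 lower adjusted over the list alone). Anpep, a peptidase of the brush border, rose from 4405 ± 902 CPM to 6419 ± 702 CPM (SD, n = 10 each; adjusted p = 0.00398), and the disaccharidase Mgam (0.50 ± 0.12) and the amino acid transporters Slc7a9 (0.38 ± 0.08) and Slc6a19 (0.36 ± 0.09) rose. The enterocyte list was called higher (camera adjusted p = 1.46e-04, median 0.18), with adjusted p = 0.332 with an estimated correlation. Control library 2 had the lowest score on these markers, -0.56 against a control mean of -0.08 ± 0.23 (SD, n = 10). Of 19 tight junction genes 4 rose and 15 were not called (5 higher and 1 lower adjusted over the list alone), namely Marveld3 (0.48 ± 0.11), Tjp3 (0.41 ± 0.10), Cldn3 (0.33 ± 0.08) and Cgn (0.34 ± 0.10), and the list was not called (camera adjusted p = 0.0823), though it was in 3 of the 20 fits without 1 library and without PFAS libraries 7 to 10 (adjusted p = 0.0374). Distal ileum markers, which share Slc51a and Slc51b with the bile acid list, had 2 of 11 higher and 1 lower, Gcg (-0.54 ± 0.12), the gene of the enteroendocrine hormone GLP-1. Adjusted over the list alone 3 were higher and 1 lower. Camera called the distal list higher (adjusted p = 0.0470, median 0.17), with adjusted p = 0.350 with an estimated correlation, and the call was lost in 12 of the 20 fits without 1 library. Proximal small intestine markers had 0 of 10 members called (camera adjusted p = 0.883).

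All 17 tested B cell markers had a positive log2 fold change and 0 were called, also adjusted over the list alone. Camera called them higher (adjusted p = 0.00488, median 0.48), with adjusted p = 0.686 with an estimated correlation. Their scores spread far within each group, from -1.80 in control library 1 to 0.59 in control library 10 and from -1.53 in PFAS library 10 to 1.52 in PFAS library 5. Of 10 plasma cell markers 2 rose and 8 were not called (3 higher adjusted over the list alone), Jchain (0.51 ± 0.10), which joins secreted antibodies, and Xbp1 (0.30 ± 0.09). The plasma cell list was called higher (camera adjusted p = 0.00582, median 0.15), with adjusted p = 0.166 with an estimated correlation.

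Of 85 tested cytosolic ribosomal protein genes 15 rose, 0 fell and 70 were not called, while 59 were higher and 1 lower adjusted over the list alone. Rpl11 rose from 563 ± 39.2 CPM to 749 ± 140 CPM (SD, n = 10 each; adjusted p = 0.00322), and Rps18 (0.47 ± 0.11), Rps27 (0.38 ± 0.09) and Rps29 (0.38 ± 0.09) rose. Camera called the list higher (adjusted p = 2.00e-18, median 0.26), with adjusted p = 0.331 with an estimated correlation. The PFAS libraries 7, 8, 9 and 10 had scores of 0.30, 0.24, 0.48 and 0.45, and the other 6 PFAS libraries lay between -0.13 and 0.04. Without these 4 libraries 0 ribosomal protein genes were called by edgeR and the median was 0.08 (camera adjusted p = 0.00396). Camera's preset correlation also called this list in 58 of 99 random splits of the libraries, which were not balanced for group.

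**Figure D3:**
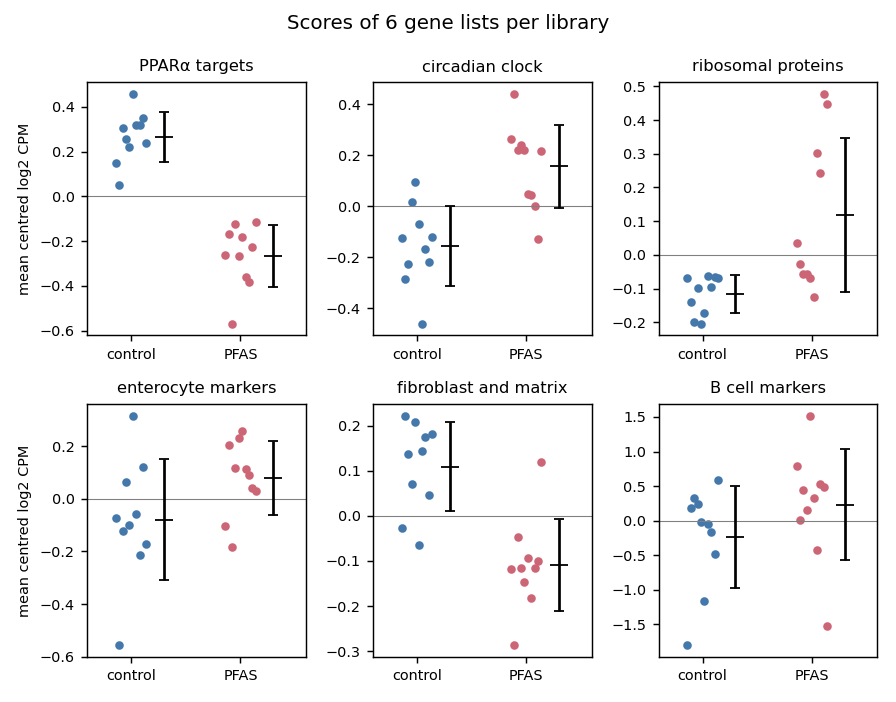
Score of 6 gene lists in each of the 10 control and 10 PFAS libraries (mean over members of log2 CPM centred on the mean of all 20 libraries); points are libraries, and the horizontal mark and bars give the mean and SD. The PPARα scores do not overlap, with means of 0.27 and -0.27, the ribosomal protein scores of 4 PFAS libraries lie above those of the other 16 libraries, and the B cell scores spread widely in both groups.

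Genes that respond to foreign compounds went both ways. Of 29 targets of the receptors CAR and PXR 3 rose, 4 fell and 22 were not called (3 higher and 6 lower adjusted over the list alone), with a camera adjusted p of 0.687. Cyp3a13 (0.49 ± 0.08), Abcb1a (0.42) and Sult2b1 (0.31) rose, and the glutathione transferase Gstm3 (-1.56 ± 0.25), the aldehyde dehydrogenases Aldh1a7 (-0.68 ± 0.14) and Aldh1a1 (-0.49 ± 0.12) and Sult1d1 (-0.30) fell. Cyp3a44, a member of the same cytochrome family that was in no list, had the largest rise of all named genes, 4.04-fold from 2.02 ± 1.68 CPM to 8.24 ± 3.65 CPM (SD, n = 10 each; adjusted p = 0.00231), and its reads cannot be fully parted from those of its paralogs. Among 25 NRF2 targets Gpx2 (0.57 ± 0.14), Srxn1 (0.36 ± 0.09) and Ftl1 (0.48) rose, Gstm3 and Txnrd1 (-0.35 ± 0.09) fell and 20 were not called (3 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.711). None of 5 AHR targets was called (camera adjusted p = 0.687). In fatty acid synthesis, Scd2, a desaturase, rose 2.06-fold and Acacb, which makes the malonyl-CoA that inhibits Cpt1a, fell by 0.82, with 13 of 15 genes not called (camera adjusted p = 0.836). Of 20 genes of chylomicron assembly and fat absorption 1 fell, the lipid droplet protein Plin2 (-0.41 ± 0.09), and 2 were higher and 5 lower adjusted over the list alone (camera adjusted p = 0.510). Abcb1a, Sult2b1, Sult1d1 and Ftl1 were named after their values were seen.

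The remaining genes with the largest changes were mostly expressed at a few CPM. Those that rose were Prss27 (1.82 ± 0.28), Pla2g5 (1.37 ± 0.33), Thpo (1.37 ± 0.28), B3galt5 (1.33 ± 0.32), Adora1 (1.30 ± 0.31) and Gml (1.20 ± 0.35). Those that fell were Gm30810 (-1.54 ± 0.38), Grin3b (-1.36 ± 0.32), Tcf23 (-1.19 ± 0.29), Arg2 (-1.18 ± 0.34), Hist1h1b (-1.17 ± 0.25), Edn1 (-1.16 ± 0.29) and G6pc (-1.15 ± 0.19), the last of which makes free glucose and went from 80.4 ± 20.6 CPM to 36.2 ± 11.3 CPM.

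The other lists were not called as sets. Among 25 unfolded protein response genes Herpud1 (0.32 ± 0.08) and Xbp1 rose (camera adjusted p = 0.126), among 23 macrophage and dendritic cell markers Mertk (0.28 ± 0.08) rose (camera adjusted p = 0.126), and among 17 goblet cell markers Fcgbp (0.28 ± 0.08) rose (camera adjusted p = 0.687). Paneth cell markers had Defa30 (0.36 ± 0.10) higher and Defa34 (-0.83 ± 0.17) lower among 20 (camera adjusted p = 0.897), and these defensins are near-identical paralogs. Among 18 enteroendocrine markers Gcg fell (camera adjusted p = 0.507), and among 20 markers of enteric neurons and glia Ncam1 (-0.28 ± 0.08) fell (camera adjusted p = 0.510). Of 7 colon markers Saa1 rose (camera adjusted p = 0.507). No gene was called among 74 nuclear-encoded oxidative phosphorylation genes (camera adjusted p = 0.0823, with the list called in 6 of the 20 fits without 1 library), 13 tuft cell markers (0.147), 21 markers of T cells and intraepithelial lymphocytes (0.155), 11 genes of MHC class II presentation (0.510), 12 heat shock genes (0.671), 15 adipocyte markers (0.678), 19 endothelial markers (0.736), 7 germinal centre markers (0.742) or 16 immediate early genes (0.983). Too few members were tested for a set test of mast cell and granulocyte markers (3), pancreatic acinar markers (3) and red blood cell markers (4), of which Hbb-bt fell by 0.72 (adjusted p = 0.0336). The pattern for mitochondrially encoded genes matched 0 of the symbols in the table, because it required the prefix mt-, which the table's symbols lack. These genes were therefore not examined as a list, and the miss says nothing on whether they were counted. Median and set test differed in sign for the chylomicron, CAR and PXR, NRF2, germinal centre, fatty acid synthesis and Paneth lists (positive median, tested lower) and for immediate early genes (negative median, tested higher).

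**Figure D4:**
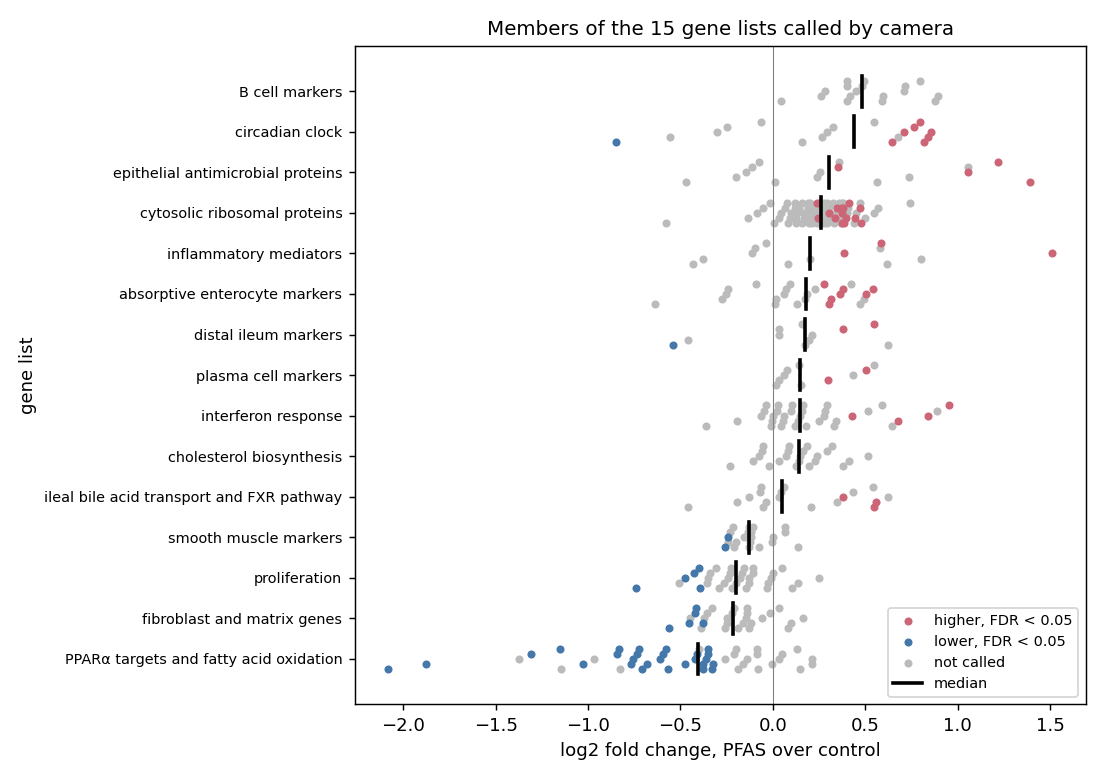
Log2 fold change (PFAS over control) of each tested member of the 15 gene lists that camera called with its preset correlation; each point is a gene, coloured where it passed FDR < 0.05, and the black bar is the list's median. The medians run from -0.41 for PPARα targets to 0.48 for B cell markers, and 27 of the 48 PPARα genes are called lower.

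In all, 605 of 12813 genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 321 higher and 284 lower in PFAS, and 2525 genes had an unadjusted p under 0.05. The changes were small, with a median absolute log2 fold change of 0.43 among called genes and more than 2-fold in 35 genes, 18 higher and 17 lower. The authors' deposited table calls 504 genes at an adjusted p under 0.05. Of these, 469 passed the count filter used here and 456 were called here too, all 456 in the same direction. With library size as the only scaling the split was 184 higher and 731 lower, with a median log2 fold change of -0.08 over all tested genes. TMM factors averaged 1.029 ± 0.030 in control and 0.972 ± 0.031 in PFAS (SD, n = 10 each), so leaving them out lowers PFAS values against control. The 20 most abundant genes took 14.9 ± 0.45% of counts in control and 16.7 ± 1.0% in PFAS (SD). Without PFAS libraries 7 to 10 the test called 292 genes, 190 higher and 102 lower, of which 215 were shared with the fit on all libraries. Fewer libraries also give less power, so the drop is not due to these libraries alone by this count. Of 40 lists tested with camera's preset correlation 15 were called, 11 higher and 4 lower, and with an estimated correlation 1 was called, the PPARα list. As many lists were called in 12 of 100 splits of the 20 libraries into groups of 10, the real split included.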

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

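The count of random splits was planned, and the other tests in this part were chosen after the data were seen. Among these, the tests on the clock covariate, the proximal covariate and length-matched genes had their bounds written before their own result was seen, and those on the enterocyte share, the clock activators with Nfil3, the glucocorticoid-induced genes, PFAS libraries 7 to 10 and the length trend after it. Both covariate fits were left out for a time, and the length bound rewritten, after their results had been seen, and all 3 stand here as first written.

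PPARα target and fatty acid oxidation genes were lower in PFAS, with a median log2 fold change of -0.41. A smaller share of enterocytes would lower enterocyte markers as well, and their median was 0.18. The fit with the proximal marker score as covariate left the PPARα median at -0.40 (camera adjusted p = 1.48e-36). This met the bound written in advance against a more distal position of the PFAS pieces. The grouping accounted for only 0.0322 of the variance of that score, so the fit could hardly have moved the median and cannot decide. Distal ileum markers were called higher in PFAS (camera adjusted p = 0.0470, median 0.17). That call was weak, with adjusted p = 0.350 with an estimated correlation and a loss in 12 of the 20 fits without 1 library. Proximal markers were not called (camera adjusted p = 0.883). Neither list decides, so a more distal position stays open. With the signed clock score as covariate the median was -0.58 and the list was still called (adjusted p = 2.01e-13), which met the bound written in advance against another clock phase at collection. That bound was wrong for this design, since the score ran from -0.98 to -0.36 in control and from 0.01 to 1.00 in PFAS. The score was made after clock genes had been seen to differ, so its separation of the groups is no independent measure of phase. Clock phase and exposure cannot be told apart with it, and both stay open.

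The 11 tested output and repressor genes of the clock had a median log2 fold change of 0.71 and the 4 genes set against them one of -0.43, namely the activators Arntl, Npas2 and Clock and the repressor Nfil3, which peaks in the opposite phase to Tef. Without Nfil3, whose value had been seen, the 3 activators had a median of -0.30, which is consistent with another phase of the daily clock in the PFAS mice, from the hour of collection or from the exposure. The 16 tested glucocorticoid-induced genes outside the clock list had a median of 0.0547 with an interquartile range of 0.59 (camera p = 0.177), with 4 called higher, among them Fkbp5 (0.93 ± 0.15, SE) and Klf9 (0.50 ± 0.08), and 1 lower. This median lay below that of the output genes by more than the range, which met the bound first set against a glucocorticoid response, but the bound was dropped after the result was seen because members called both ways leave a median near 0 undecided, so a response in part of these genes cannot be told apart from none. Fkbp5 and Klf9 were named after their values were seen.

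Of 85 ribosomal protein genes 15 were called higher in PFAS, with a median of 0.26 (camera adjusted p = 2.00e-18, and adjusted p = 0.331 with an estimated correlation). Without PFAS libraries 7 to 10 the median was 0.0837 with 0 genes called by edgeR and a camera adjusted p of 0.00396, so a shift in these 4 libraries alone cannot be told apart from a weaker shift in all. The 255 other genes matched on transcript length had a median of 0.0696, or 0.265 of that of the ribosomal protein genes, between the bounds of 0.25 and 0.5 written in advance, so a technical shift of short transcripts as part of the source cannot be told apart. Removal of the length trend left a median of 0.211, from 0.24 with the trend in place (camera adjusted p = 5.92e-14). This argues against that trend as the whole source. Both length tests used the longest transcript of each gene (median 1059 bases for the ribosomal protein genes), which need not be the one expressed. A trend on the expressed length was not tested. PFAS libraries 7 to 10 come last in the numbering of the count columns, and whether they were handled apart is not given. An effect of the exposure stays open, untested.

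Chance in the grouping of the libraries is argued against for the number of genes, though 100 splits cannot exclude it. Of 100 splits of the 20 libraries into groups of 10, only 1, the real one, gave as many as 605 genes. The highest of the other splits gave 9. The splits take the libraries as interchangeable, so they do not test a difference tied to the order of the samples, which follows the group. For the number of gene lists chance cannot be excluded, since 12 of 100 splits gave as many as 15, and the highest of the others gave 19. The other splits had been drawn once before, and that draw gave fewer splits with as many lists but also left chance open. Taken list by list, an adjusted p as low as the real one came from 0 of the 99 other splits for the PPARα, circadian clock, fibroblast and matrix and inflammatory mediator lists, and from 1 for plasma cell markers. It came from 5 for the bile acid and enterocyte lists, 6 for smooth muscle, 7 for ribosomal proteins, 8 for antimicrobial genes, 9 for proliferation, 10 for distal ileum, 15 for interferon, 31 for cholesterol biosynthesis and 33 for B cell markers. A call at the preset correlation was common in the other splits, with 58 of 99 for ribosomal proteins, 51 for the PPARα list and 50 for B cell markers. The splits were not balanced for control and PFAS libraries, so some carry part of the real group difference. These counts are therefore not a pure rate of false calls. The lowest adjusted p of the PPARα list in the other splits was 7.34e-16, against 1.56e-41.

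In 13 of 290 groups of 10 values 1 library stood far from the nearest of the others relative to the group's range, and chance flags about 1 in 20 groups. These groups cover genes named in the text, a limit set after a first look at all genes of the naming rule, and over all 196 tested genes of that rule or named later it was 21 of 476 groups. The values below are this gap divided by the range. Control library 2 was lowest for Anpep (0.813), Socs3 (0.518), Npc1l1 (0.505) and Xbp1 (0.499). Control library 6 was lowest for Adora1 (0.582) and Rpl11 (0.499), and control library 8 for Reg3g (0.511). Among PFAS libraries, number 2 was highest for Abcg5 (0.53) and lowest for Reg3b (0.569), number 5 was lowest for Gcg (0.499) and highest for the tuft cell score (0.766), number 9 was lowest for Herpud1 (0.493), and number 10 was highest for Grin3b (0.573).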

How the results depend on the processing

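The alternatives that set libraries aside, removed the length trend or took a clock or proximal score as covariate were chosen after seeing the data. Of 95 called genes named in the text, 73 were called in each of the 20 fits without 1 library, and the call was lost in at least 10 of these fits for 14 (Abcg5, Acta2, Defa30, Duox2, Gml, Ifit1bl1, Il18, Mertk, Myh11, Ncam1, Nfkbie, Nusap1, Sult2b1 and Xbp1). Library size as the only scaling gave 915 genes, 184 higher and 731 lower. Without PFAS libraries 7 to 10 there were 292 genes, 190 higher and 102 lower, and without control 1, control 2 and PFAS 10 there were 504 genes, 332 higher and 172 lower. Leaving out 1 library gave 186 to 318 genes lower, the lowest without PFAS library 9. Of the 95 genes, 48 were called without PFAS libraries 7 to 10. That fit has fewer PFAS libraries and so less power, and no other set of PFAS libraries of that size was left out. The lost calls therefore cannot be laid to these libraries alone. Camera with an estimated correlation called 1 list in place of 15. Fry lost the cholesterol biosynthesis (0.294), interferon (0.0570) and B cell (0.310) lists, ranks the bile acid (0.166), inflammatory (0.0874), antimicrobial (0.0550) and distal ileum (0.0837) lists, and setting aside PFAS libraries 7 to 10 the inflammatory and antimicrobial lists (adjusted p in brackets). That last setting called 18 lists in all, since it gained the cholesterol absorption (0.0175), tight junction (0.0374), Paneth (3.73e-04), enteroendocrine (0.0404) and red blood cell lists. The oxidative phosphorylation list was gained with ranks (0.0317), the proximal score (0.0120), the clock score (2.10e-07) and in 6 of the 20 fits without 1 library, and the T cell list with library size only (0.0432). The distal list was also lost with library size only (0.0672), and it and cholesterol biosynthesis with a mean of at least 5 CPM (0.0678 and 0.0532) or the proximal score (0.0972 and 0.128). Limma-trend lost both and the bile acid list, and without the length trend the inflammatory list too (0.0744). Leaving out the TMM factors lowers PFAS values against control, which goes with the split under library size only. The cause of the other shifts was not tested.

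With the clock score as covariate edgeR called 0 genes, 0 higher and 0 lower (1101 with an unadjusted p under 0.05), and camera called 8 lists. Of the 15 called without it 11 were lost and 4 kept, 3 had the other direction, and the goblet list (0.0329) was among the 4 gained. The score separates the groups completely, so this fit leaves little of the group difference to test. Of the 605 called genes 24 changed sign, 6 of them named in the text, Abcg5 (-0.0367), Cgn (-0.22), Col3a1 (0.12), Fkbp5 (-0.0534), Mertk (-0.0519) and Slc6a19 (-0.03). In the other settings 0 of the 95 did. Of uncalled genes Abcg8 (-0.17), Fgf15 (0.21), Itln1 (0.42) and Slc10a2 (-0.0061) changed sign. Lists that turned had adjusted p of 1.04e-05 (Paneth, then called higher), 0.0045 (adipocyte, then called lower), 0.386 (circadian clock), 0.240 (proliferation), 0.868 (cholesterol biosynthesis and germinal centre), 0.396 (cholesterol absorption), 0.186 (immediate early), 0.821 (proximal), 0.326 (enteroendocrine) and 0.735 (stem cell). The proximal score turned Fabp6 (-0.0022) and the immediate early (0.880), proximal (0.682) and Paneth (0.766) lists.

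The replicate block gave 615 genes (520 shared) and 15 lists, and called Slc10a2 (adjusted p = 0.0162). Same-numbered libraries did not deviate together, with correlations from -0.103 to 0.0965 over 10 pairs, and 0 libraries correlated best with their own number. The block turned the uncalled immediate early list (adjusted p = 0.877).

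Other changes of direction were among values that were not called. Fabp6 was -0.0547 with library size only and ran from -0.0411 to 0.115 without 1 library. Hmgcr ran from -0.0749 to 0.0325 without 1 library, was 0.14 without PFAS libraries 7 to 10 and 0.0028 without control 1, control 2 and PFAS 10. Some uncalled lists turned in 1 or more of the fits without 1 library, and over all 20 fits, turned or not, their adjusted p were 0.661 to 0.987 (immediate early), 0.678 to 0.989 (proximal), 0.356 to 1.00 (Paneth), 0.238 to 0.998 (fatty acid synthesis), 0.359 to 0.780 (adipocyte), 0.284 to 0.922 (chylomicron), 0.255 to 0.962 (CAR and PXR) and 0.513 to 0.987 (endothelial). Library size only turned the proximal list (0.955), a mean of at least 5 CPM the immediate early (0.989) and proximal (0.983) lists, and ranks the immediate early and Paneth lists (both 0.917). Without PFAS libraries 7 to 10 the fatty acid synthesis and heat shock (both 0.778), AHR (0.846), goblet (0.873) and oxidative phosphorylation (0.403) lists turned. Without control 1, control 2 and PFAS 10 the immediate early (0.690) and adipocyte (0.583) lists turned, and without the length trend the immediate early (0.769) and goblet (0.993) lists.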
